A study of Pinus armandii with 6 samples.

How the data were processed

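RNA sequencing was done on seed kernels of Pinus armandii, with 3 libraries from cones harvested at the end of August and 3 from cones harvested at the end of September. The labels call the libraries of a month biological replicates. They do not say whether each came from its own tree, cone or pool of seeds, so p-values measure the spread between these libraries, part of which can be technical.

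Reads were trimmed with fastp and quantified with RSEM, per the submitters' processing notes, which give no versions. The assembler, the annotation programs, the library kit and its strandedness are not given in the sources used here. The deposited table holds estimated counts per unigene and library, not normalized, per the file headers. A unigene is a transcript sequence assembled from the reads, so 1 gene can be split over several unigenes, and reads of near-identical copies can be divided between them. The same table holds FPKM values made by the authors, per the file headers. The ratio of count to FPKM gave 1 length per unigene with a relative SD of at most 0.000166 over 6 libraries, in the 8157 unigenes with 200 counts or more. The FPKM values therefore carry no scaling beyond total counts and length. The table has 65117 unigenes and each has a count in at least 1 library. Of 390702 count values, 8 were not whole, and all were rounded to whole numbers. Every per-sample column matched 1 library.

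The deposited annotation gives a best database hit for 30124 unigenes (46.3%), a gene symbol for 21783, a KEGG pathway for 7036 and a transcription factor family for 755. Of the best hits, 22122 read unknown, hypothetical, uncharacterized, unnamed or predicted protein. Best hits were sorted by the genus in the hit into gymnosperm (19538 unigenes), other plant or alga, and non-plant (494). Names are those of the hit or of the symbol column. They mark resemblance, and the symbol and the hit of a unigene can differ. No genome was used, so positions are not given.

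Total counts per library ran from 12849649 to 17379628. Where a month had no counts, the fold was bounded with a floor of 3 counts over the 3 libraries, which is 0.0663 CPM (counts scaled to library size in the usual way) in August and 0.0671 CPM in September. Where a month had 1 to 3 counts, the ratio is given with an exact 95% counting interval. Floors and intervals cover counting error only.

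Gene tests used edgeR 4.0.16 in R 4.3.3 on the rounded estimated counts, with TMM size factors (0.993 to 1.01), filterByExpr by month at its defaults (minimum count 10, minimum total count 15, minimum group of 3 libraries), the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. Adjusted p-values of single genes come from this test unless another is named. Standard errors were derived from the F statistic. CPM values of single genes are relative to counts in tested genes, which held 98.6% to 99.7% of the counts of a library, and include the TMM factor.

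Before the data were examined, 24 gene lists were fixed as text patterns matched on the best-hit description. For each, the tested members higher and lower were counted, with p-values adjusted over all tested genes and again over the list alone. The list was also tested with camera in limma 3.58.1, which asks whether its members moved differently from other genes, at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 24 lists. The summed share of counts of a list was compared by an exact two-sided permutation test over 20 orderings, whose smallest possible p is 0.1. KEGG pathways with 10 to 500 tested genes were tested with camera in the same way. Some members of the defence list matched only through a locus number beginning with PR202, which is no evidence of a defence role, and the list was also run without them. Because many descriptions read unknown, wider lists that add members by gene symbol were made after the data were seen. Symbols place a unigene in a family and can name a related enzyme, so the wider lists are approximate.

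The genes to be named were chosen by a rule fixed beforehand. It took the 5 largest rises and 5 largest falls among passing genes with an informative description, a mean of 20 CPM or more and no overlap between months. It also took the most abundant member of each list, the passing member of each list with the largest change and a mean of 5 CPM or more, and the 5 most abundant genes. The same rule was applied to the wider lists, as a choice made after seeing the data.

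Replicates were compared by Pearson correlation of log2(CPM + 1), principal components and a chi-square statistic per gene. The pipeline was tested on simulated counts for this comparison. With 200 genes changed among 22405, it recovered 24 of 50 at 1.5-fold, 40 of 50 at 2-fold, 50 of 50 at 4-fold, 50 of 50 at 8-fold and 14 of 20 further genes that were shifted 2-fold as a simulated list. Of 188 calls in all, 10 were false (5.32%). With no gene changed among 22385, it made 0 calls. The simulated list of 20 genes was called with both correlations, and 0 of 29 random lists were. Simulated genes were drawn independently of each other, and far fewer changed than the 15750 of 23216 called in the data. The simulation therefore does not test camera on correlated genes, or recovery when most genes change.

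The alternatives were RLE size factors, total counts, TMM without the 50 most abundant genes, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), and glmTreat against a log2 fold change of 1. Further ones were no filter, a stricter filter of 1 CPM in all 3 libraries of a month, a replicate block, leaving out each library, summing unigenes of the same best hit, and unigenes of 500 bases or longer. Leaving out non-plant hits, matching any description column, and fry were also run. Chosen after seeing the data were a fit on unigenes with a gymnosperm best hit only, the wider lists, the defence list without the PR202 matches, lists of organelle-encoded transcripts, transcription factor families, and list members split by best hit. For each gene named outside the rule, the sum over its best hit and the fits without 1 library were also looked up, and members of the wider and organelle lists, pathways and families were counted without each library and with no filter. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.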

Results

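Seed kernels of Pinus armandii, the Chinese white pine, whose large seeds are eaten as pine nuts, were profiled by RNA sequencing at 2 harvests. Cones were taken at the end of August or at the end of September, and 3 libraries were made for each month. A pine kernel holds the embryo inside a storage tissue, the megagametophyte, which accumulates protein and oil as the seed matures. Estimated counts were available for 65117 unigenes, the assembled transcripts of this species. Total counts were 16131203, 13610427 and 15734657 in the August libraries and 14845783, 17379628 and 12849649 in the September libraries. Between 38279 and 40994 unigenes had a count in an August library, and between 43216 and 46495 in a September library. The 10 most abundant unigenes of a library took 4.78% to 5.2% of its counts in August and 7.91% to 8.19% in September.

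The libraries of a month resembled each other more than those of different months. Across unigenes, which are not independent replicates, the Pearson correlation of log2(CPM + 1) was 0.98 to 0.993 within a month and 0.93 to 0.95 between months. The first principal component held 76% of the variance and parted the months. The second held 12% and set the second August library, at -64.2, apart from the other August libraries, at 34.2 and 39.8. No pair of libraries agreed within sampling noise, since the chi-square statistic per unigene was 5.05 to 13.5 within months, and all 6 were counted as separate samples.

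The comparison of the months asked how kernel gene expression changed over the harvesting period. A broad shift was measured. Single genes that rose by September included the fatty acid dioxygenase DOX1, HSP70, HSP90-1, the wall endoglucanase KOR, a flavanone 3-hydroxylase, a linker histone and 2 isocitrate lyase unigenes. Those that fell included the most abundant listed oleosin, an Em-like late embryogenesis protein, a dehydrin, a defensin, and PR10 and thaumatin-like proteins. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 15750 of 23216 tested unigenes (67.8%) passed, 8209 higher in September and 7541 lower. Rises were larger: 5633 passing unigenes were at least 2-fold higher and 2886 at least 2-fold lower. In 16916 tested unigenes (72.9%, where chance gives 10%) the 3 libraries of one month all lay above those of the other. Without the second August library, 15547 unigenes passed, 8309 higher and 7238 lower.

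**Figure D1:**
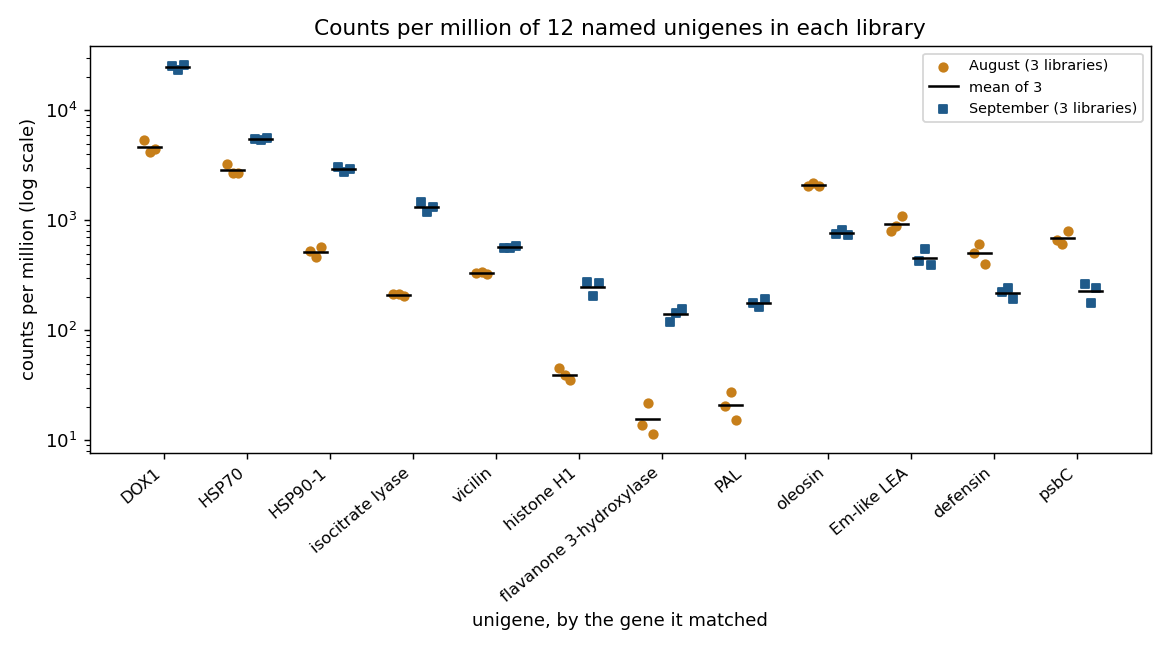
Counts scaled to library size (CPM, log axis) of 12 named unigenes in the 3 August libraries (circles) and the 3 September libraries (squares), with the mean of each month as a bar. No unigene shown has libraries of the 2 months overlapping, and DOX1 reached a mean of 24911 CPM in September.

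The most abundant transcript of the September kernels was DOX1 (Unigene0000577), an alpha-dioxygenase of the kind that oxidises fatty acids. It rose from 4660 ± 621 CPM in August to 24911 ± 1249 CPM in September (SD, n = 3 each; log2 fold change 2.42, SE 0.0972, adjusted p = 6.0e-08 by edgeR). The translation elongation factor EF-1alpha (REFA1, Unigene0002528) rose from 4327 ± 413 to 10226 ± 384 CPM. Unigene0000914, which has no database hit, rose from 5908 ± 641 to 9600 ± 609 CPM. The others of the 5 most abundant unigenes fell. A cytochrome P450 (CYP750A1, Unigene0001415) went from 11039 ± 286 to 8062 ± 272 CPM and an RNA-binding protein (RBM47, Unigene0068140) from 6026 ± 160 to 4730 ± 115 CPM.

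Among genes with an informative best-hit description, a mean of 20 CPM or more and no overlap between months, the largest rises were in a cytochrome P450 (CYP92C6, Unigene0023296; log2 fold change 8.23, SE 0.479), a fasciclin-like arabinogalactan protein of the cell wall (FLA10, Unigene0053714; 5.77, SE 0.169) and a galacturonosyltransferase-like protein (GATL7, Unigene0022022; 5.65, SE 0.334). Summing all unigenes with the best hit of CYP92C6 left a log2 fold change of 1.69 (adjusted p = 4.4e-05), and GATL7 had 6.43 without the first August library. A RING finger protein (ATL23, Unigene0037926) rose from 4.84 ± 0.743 to 211 ± 44.5 CPM. A ginkbilobin-like antifungal protein, also called embryo-abundant protein (EAP, Unigene0032100), rose from 4.46 ± 1.98 to 185 ± 17.1 CPM. The 5 largest falls under the same limits follow. A TIR-NBS-LRR protein, a class of immune receptors (L6, Unigene0000861), fell from 47.4 ± 8.69 to 0.587 ± 0.0602 CPM, but summing all unigenes with that best hit gave a log2 fold change of 0.96 (adjusted p = 4.1e-05), the opposite direction. A germin-like protein (At5g39130, Unigene0040311) fell by 4.97 on the log2 scale, a cysteine-rich repeat secretory protein (Unigene0012989) by 4.16, a PR10 protein (Fra, Unigene0037022) by 3.65 and a thaumatin-like protein (TLP, Unigene0029214) by 3.50, with standard errors of 0.115 to 0.324. Without the first September library, At5g39130 fell by 5.78 and Fra by 4.24.

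Of the 24 gene lists fixed before the data were examined, 6 moved apart from the other genes, all of them higher in September. They were seed storage proteins, small heat shock proteins, large chaperones, lipid breakdown with the glyoxylate cycle, flavonoid synthesis, and cell wall loosening and expansion. The calls come from camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment. With an estimated correlation 0 of the lists passed, 4 had an unadjusted p under 0.05, and the smallest adjusted p was 0.229. Of lists that did not pass, fry, which tests against no change, called the raffinose (adjusted p = 0.000921), histone (0.00371) and lignin (0.00556) lists higher on balance and the ribosomal list lower (0.0132), and 5 others are given with their values. The lists held 359 tested members, of which 151 were higher and 126 lower. Counts adjusted over the list alone equalled those over all tested genes in all lists but 4, which are named with their values. The median, the mean and the camera direction differed in sign for LEA proteins, lipid droplet proteins, fatty acid synthesis, desaturases, starch and sucrose, embryo regulators, cell cycle and antioxidant enzymes, none of which passed.

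**Figure D2:**
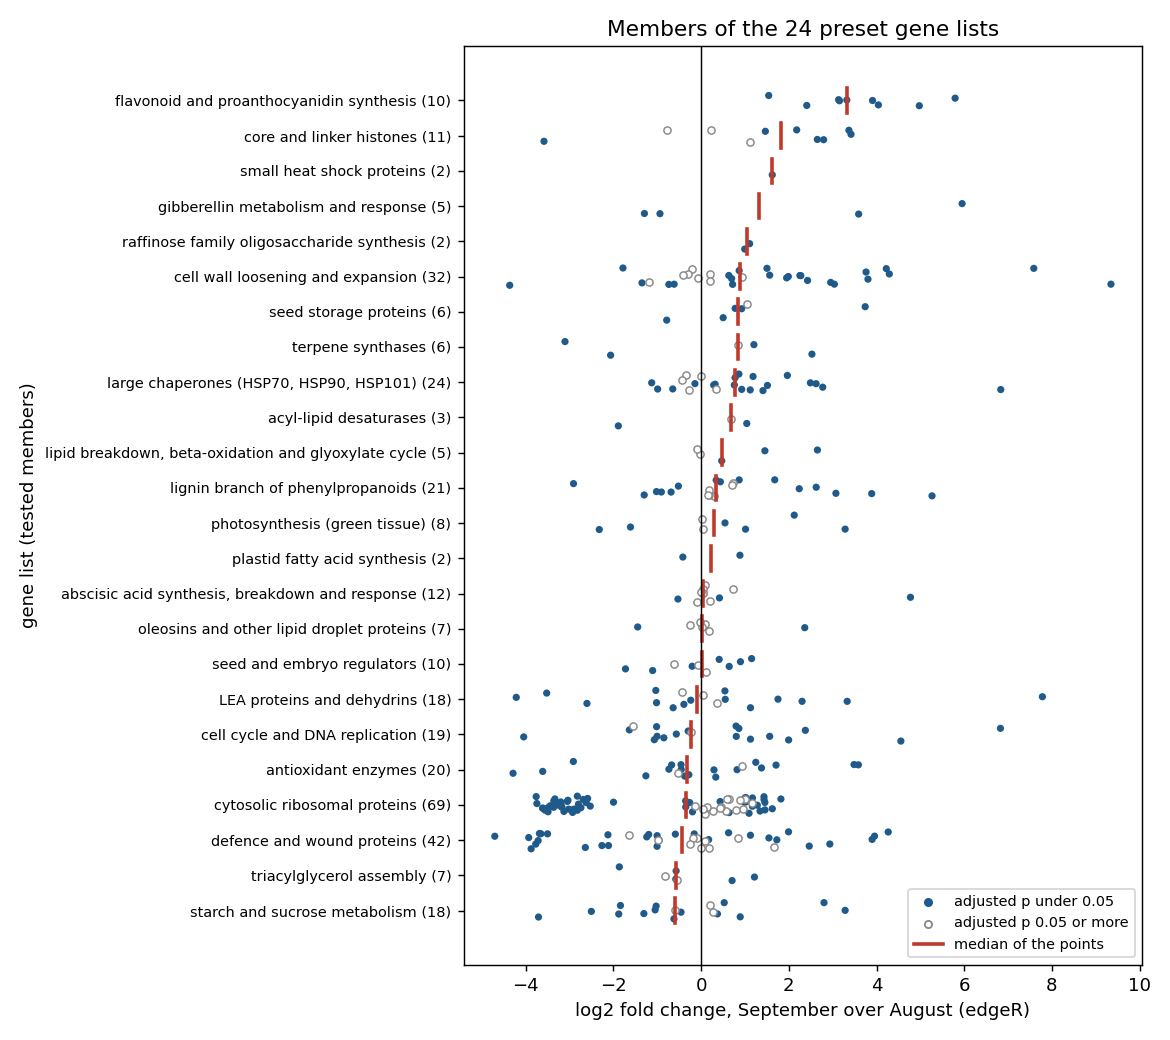
Log2 fold change, September over August, of 350 tested members of the 24 gene lists, 1 point per member. Filled points passed the edgeR test, open points did not, and bars mark the median of the points. 9 members with no count in a month are left out, since their fitted value is no bound. All drawn points of the flavonoid list lie above 0.

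Of 6 tested storage protein members, 4 were higher, 1 was lower and 1 did not pass (adjusted p = 0.0142 for the list, and 0.229 with an estimated correlation). A further member too low for the test was tested as lower, making 2, without the third August library or any single September library. The vicilin AMP2-1 (Unigene0070812), a 7S globulin that pine seeds store, rose from 332 ± 7.74 to 568 ± 15.8 CPM, and a second vicilin unigene (Unigene0070811) from 2.77 ± 0.614 to 36.9 ± 2.78 CPM. The 2 share a best hit, so reads can be divided between them, and their sum had a log2 fold change of 0.89 (adjusted p = 4.4e-07), against 3.74 for Unigene0070811 alone. The list's summed share of counts went up 1.64-fold (exact permutation p = 0.1, the smallest possible), while that of the wider list of 15 members, made after the data were seen, was 6742 ± 289 CPM in August and 6843 ± 661 CPM in September (exact permutation p = 1). The list call was lost without the third August library (adjusted p = 0.277) and when unigenes with the same best hit were summed (adjusted p = 0.0986).

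Desiccation proteins moved both ways. Of 18 late embryogenesis abundant (LEA) proteins and dehydrins, which protect drying cells, 7 were higher and 8 lower (list adjusted p = 0.916). The summed share of the list went from 2904 ± 162 to 2115 ± 108 CPM (exact permutation p = 0.1, the smallest possible). The most abundant member, an Em-like protein (Unigene0069821), fell from 927 ± 151 to 457 ± 86.8 CPM, and a dehydrin (Unigene0066223) fell by 4.22 on the log2 scale (SE 0.353).

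Both tested small heat shock proteins were higher (list adjusted p = 0.0111, and 0.229 with an estimated correlation). HSP23 (Unigene0062075) rose from 31.1 ± 2.93 to 95.9 ± 7.30 CPM. The other member, whose best hit is not a gymnosperm, stood at 0 CPM in August and 5.16 CPM in September, so its fitted fold change is no bound. The list call rests on these members alone. Of 24 large chaperones, which fold and hold other proteins, 15 were higher, 4 lower and 5 did not pass (adjusted p = 0.000243). With an estimated correlation the adjusted p was 0.229. HSP70 (Unigene0070431) rose from 2890 ± 328 to 5483 ± 142 CPM and HSP90-1 (Unigene0019526) from 519 ± 52.3 to 2919 ± 157 CPM. With no filter 17 of 75 were higher and 11 lower, and with same-hit unigenes summed 2 were lower. The call of the large chaperones was lost when only unigenes with a gymnosperm best hit were used (adjusted p = 0.634), where 3 of 7 members were higher and 1 lower, and when any description column was matched (adjusted p = 0.119). In the wider list of small heat shock proteins, made after the data were seen, 28 of 35 members were higher and 3 lower (adjusted p = 1.0e-21). With an estimated correlation the adjusted p was 0.134. Its most abundant member, HSP18.1 (Unigene0001567), rose from 2245 ± 154 to 5307 ± 143 CPM.

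Oil-related genes moved both ways. Among 7 lipid droplet proteins 1 was higher, 1 lower and 5 did not pass (list adjusted p = 0.987). There were 2 higher without the second August library or with same-hit unigenes summed, and 2 lower without the first August library, without the second September library or with no filter. With the replicate block 2 were higher and 2 lower. The most abundant member, an oleosin (Unigene0045277), a coat protein of oil bodies, fell from 2096 ± 94.99 to 768 ± 47.5 CPM, whereas a caleosin (SOP1, Unigene0069223) rose from 11.4 ± 0.820 to 58.8 ± 4.70 CPM. Summed with the other unigene of its best hit, SOP1 had a log2 fold change of 0.26 (adjusted p = 0.00541), against 2.36 alone. The summed share of the lipid droplet list went to 0.574 of its August value (exact permutation p = 0.1, the smallest possible). That of the wider lipid droplet list went to 0.918 (exact permutation p = 0.3). There 8 of 19 members were higher and 5 lower (camera adjusted p = 0.985), or 8 of 25 higher and 8 lower with no filter. In lipid breakdown and the glyoxylate cycle, 3 of 5 members were higher and 2 did not pass (adjusted p = 0.047, and 0.330 with an estimated correlation). Isocitrate lyase, which turns fatty acid carbon toward sugar, accounts for 3 of the 5 members. Its unigenes rose from 211 ± 6.80 to 1329 ± 136 CPM (Unigene0037351) and from 1410 ± 109 to 1952 ± 78.2 CPM (Unigene0062588), and Unigene0075079 stood at 2.27 and 2.13 CPM (adjusted p = 0.843). The last 2 share a best hit, and their sum had a log2 fold change of 0.50 (adjusted p = 0.000104). The other riser was a ketoacyl-CoA thiolase of beta-oxidation (KAT5, Unigene0072913; log2 fold change 1.45, adjusted p = 0.0212), whose call was lost without the first August library (1.14, adjusted p = 0.0838), the third August library (1.44, 0.0538) or the second September library (0.87, 0.138). This list call was lost without any single August library (adjusted p = 0.0542 without the first, 0.0853 without the second and 0.0773 without the third), with no filter (0.184, with 3 of 12 members higher and 4 lower), with any description column matched (0.629) and in the wider list, where 10 of 35 members were higher and 9 lower (0.973). The most abundant member of the wider list, the thiolase PED1 (Unigene0064391), went from 1844 ± 48.2 to 1671 ± 76.9 CPM (adjusted p = 0.0473, a call lost without the second August library (0.0564) and without the second or the third September library (0.103 and 0.195)).

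No list for making oil stood apart from other genes by camera. Against no change, fry called triacylglycerol assembly (adjusted p = 0.00092) and desaturases (adjusted p = 0.016) lower on balance. In the wider lists, fry called triacylglycerol assembly lower (adjusted p = 0.00087) and fatty acid synthesis higher (0.0041), and the desaturases did not pass (0.108). Plastid fatty acid synthesis had 1 of 2 members higher and 1 lower (list adjusted p = 0.916), with a fall of fabZ (Unigene0035375) from 93.2 ± 2.77 to 69.7 ± 3.19 CPM. None of its members was higher without the first or the third August library, without the second September library, with no filter or with the replicate block. Of 3 unigenes matched by description as acyl-lipid desaturases, 1 was higher and 1 lower, with a median log2 fold change of 0.682 (list adjusted p = 0.709). FAD8 (Unigene0005158), which makes trienoic fatty acids in plastids, rose from 68.9 ± 3.38 to 142 ± 11.9 CPM. The only member passing as lower was sld1 (Unigene0058363), which fell from 135 ± 4.65 to 36.4 ± 2.45 CPM. Whether sld1 acts in making oil was not tested. In triacylglycerol assembly 2 of 7 members were higher and 3 lower, or 4 lower adjusted over the list alone (list adjusted p = 0.680). None of these 7 has a gymnosperm best hit. RAM2 (Unigene0014699), a glycerol-3-phosphate acyltransferase, rose by a log2 fold change of 0.71 (SE 0.0997), and the phosphatase LPP2 (Unigene0051028) fell by 1.87 on the log2 scale (SE 0.115). In the wider triacylglycerol list 7 of 34 members were higher and 17 lower, and its summed share went to 0.761 of its August value (camera adjusted p = 0.154). Without the second August library, or with no filter, 4 were higher and 16 lower. The most abundant members of the wider lists for making oil fell, the acyltransferase PDAT1 (Unigene0043175) from 603 ± 41.8 to 359 ± 6.43 CPM, the desaturase FAD6 (Unigene0070454) from 570 ± 18.5 to 362 ± 17.9 CPM and the synthase KAS3B (Unigene0073479) from 379.5 ± 12.1 to 313 ± 24.98 CPM. Other members rose. In the wider desaturase list 4 of 8 were higher and 2 lower, and in wider fatty acid synthesis 7 of 19 were higher and 7 lower.

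Carbohydrate genes showed both directions. Of 18 starch and sucrose members 6 were higher and 9 lower (list adjusted p = 0.294), and fry called the list lower on balance (adjusted p = 0.00138). With same-hit unigenes summed, 3 were higher and 5 lower. The invertase CINV2 (Unigene0068408) rose from 305 ± 28.0 to 440 ± 10.2 CPM, and the beta-amylase BAM3 (Unigene0071996) fell from 23.6 ± 4.52 to 1.83 ± 0.660 CPM. In the wider list 16 of 64 were higher and 29 lower (adjusted p = 0.0155, and 0.134 with an estimated correlation). There the granule-bound starch synthase WAXY (Unigene0001295) fell from 2607 ± 196 to 1201 ± 72.7 CPM. Both tested raffinose-family members were higher (list adjusted p = 0.200, 0.0303 with no filter, and 0.668 with an estimated correlation), among them the galactosyltransferase RFS2 (Unigene0007742), which rose from 486 ± 20.9 to 967 ± 87.9 CPM. Neither member has a gymnosperm best hit.

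Hormone and embryo lists did not stand apart from other genes by camera. Against no change, fry called the abscisic acid list (adjusted p = 0.0164) and the gibberellin list (adjusted p = 0.0114) higher on balance, and embryo regulators did not pass (0.127). For the wider lists, fry called gibberellin (adjusted p = 0.00112) and embryo regulators (0.000558) higher, and abscisic acid did not pass (0.225). Of 12 abscisic acid members 3 were higher, 1 lower and 8 did not pass (list adjusted p = 0.903). DPBF3 (Unigene0036330), a bZIP factor of abscisic acid response, fell from 291 ± 12.4 to 202 ± 5.38 CPM, and an ABI3-interacting protein (Unigene0004792) stood at 294 ± 32.6 and 301 ± 11.6 CPM (adjusted p = 0.705). Of 5 gibberellin members 3 were higher and 2 lower (list adjusted p = 0.916). The median log2 fold change was 3.59, while the summed share went to 0.53 of its August value with the fall of the receptor GID1C (Unigene0059676) from 86.3 ± 7.46 to 35.1 ± 4.26 CPM. The share of the wider gibberellin list was 1.07 of its August value (exact permutation p = 0.3). Among 10 embryo regulators 4 were higher and 3 lower (list adjusted p = 0.987). VP1 (Unigene0069436), the maturation regulator known as ABI3 in Arabidopsis, rose from 138 ± 2.88 to 256 ± 13.1 CPM, and WOX8 (Unigene0072719) rose by a log2 fold change of 1.15 (SE 0.191).

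The list of cell wall loosening and expansion also takes in endoglucanases and cellulose synthases by its text patterns, so it does not measure loosening alone. In this list 19 of 32 members were higher, 5 lower and 8 did not pass (adjusted p = 0.00204, and 0.229 with an estimated correlation). Without the third September library 8 of 34 were lower, and with no filter 9 of 56 were, with 19 and 20 higher. The endoglucanase KOR (Unigene0003257) rose from 108 ± 3.01 to 178 ± 1.38 CPM. The xyloglucan endotransglucosylase XTH22 (Unigene0061735), which cuts and rejoins wall xyloglucan, had 1 count in August and 870 in September, with a 95% counting interval of 158 to 34810 for the ratio. Its fitted log2 fold change was 9.34, against 8.09 with the unigenes of its best hit summed. The first August library held the August count, so the fitted 11.18 without that library compares against a month with no counts and is no bound. In the wider list 61 of 102 members were higher and 14 lower, and the call held with an estimated correlation (adjusted p = 0.0118). The most abundant member of the wider list, the cellulose synthase CESA7 (Unigene0001832), stood at 1675 ± 38.2 and 1821 ± 140 CPM (adjusted p = 0.127). Of 19 cell cycle and replication members 9 were higher and 8 lower (list adjusted p = 0.987), with falls of the replication proteins RPA1A (Unigene0009065) from 107 ± 11.2 to 59.6 ± 2.09 CPM and ORC4 (Unigene0051337) from 29.996 ± 3.28 to 14.3 ± 0.987 CPM. Of 11 histones 6 were higher and 2 lower, or 7 and 3 adjusted over the list alone (list adjusted p = 0.138, and 0.808 with an estimated correlation). Only 1 of the 11 has a gymnosperm best hit. Linker histone H1 (Unigene0002669) rose from 39.7 ± 5.03 to 250 ± 38.6 CPM. The histone list passed without the second September library (adjusted p = 0.0238) and in its wider form, with 25 of 49 members higher and 11 lower (adjusted p = 0.0155, and 0.793 with an estimated correlation). With no filter 9 of 25 members of the first histone list were higher and 6 lower.

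All 10 tested members of the flavonoid and proanthocyanidin list were higher in September, with a median log2 fold change of 3.62 (adjusted p = 0.000243). With an estimated correlation the adjusted p was 0.330. The list matched 25 unigenes, of which 15 had too few counts for the test, and with no filter 15 were higher and 3 lower. Without the third August library or any single September library, further members entered the test and 1 of them was lower, while the 10 stayed higher. Flavanone 3-hydroxylase (AN3, Unigene0020291) rose from 15.8 ± 5.58 to 140 ± 19.8 CPM. A chalcone synthase unigene (CHS, Unigene0071706), for the first step of the pathway, had 0 counts in August and 605 in September, which makes it at least 213-fold higher. The sum of the unigenes with its best hit had a log2 fold change of 8.97. A further flavanone 3-hydroxylase outside the list (AN3, Unigene0020292), singled out after its values were seen, stood at 1.04 and 1.11 CPM (adjusted p = 0.896). The summed share of the list went up 7.4-fold. In the wider list 33 of 57 members were higher and 14 lower (adjusted p = 0.0090, and 0.134 with an estimated correlation), and its summed share went up 1.35-fold, from 817 ± 140 to 1099 ± 18.4 CPM. Its most abundant member, an anthocyanidin synthase (ANS, Unigene0067650), fell from 123.3 ± 28.0 to 88.3 ± 6.78 CPM (adjusted p = 0.0127, and 0.0537 without the third September library). An anthocyanidin reductase (ANR, Unigene0074442), chosen after its values were seen, fell from 134 ± 7.62 to 65.6 ± 9.88 CPM (adjusted p = 1.1e-05). The lignin branch, which shares its first enzymes, had 9 of 21 members higher and 6 lower (list adjusted p = 0.916), 5 of 22 higher and 6 lower without the third August library, and 11 of 36 higher and 10 lower with no filter. One phenylalanine ammonia-lyase (PAL, Unigene0013949) rose from 21.2 ± 6.07 to 177 ± 15.5 CPM, and a cinnamate hydroxylase (CYP73A4, Unigene0074878) stood at 382 ± 24.9 and 431 ± 58.5 CPM (adjusted p = 0.118). Both lists were fixed as candidates for residual seed coat.

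Of 69 tested ribosomal protein members 17 were higher and 37 lower, or 18 and 37 adjusted over the list alone (list adjusted p = 0.0838, and 0.668 with an estimated correlation). The number higher was 6 without the first August library, 8 without the second, 10 without the second September library, 9 without the third, and 6 with same-hit unigenes summed, while 37 to 46 were lower in the fits without 1 library and 97 of 196 with no filter. Members with a gymnosperm best hit numbered 3, of which 0 were higher and 2 lower (median log2 fold change -0.20), and the other 66 had a median of -1.18. The difference between the classes was not tested. The member with the largest change at a mean of 5 CPM or more was a 60S P0-like unigene (Rplp0, Unigene0049632), which fell from 10.8 ± 3.90 to 0.868 ± 0.315 CPM, or by 3.61 on the log2 scale. The sum of the unigenes with its best hit fell by 1.44 (adjusted p = 0.000269). The ribosomal protein L15 (SB62, Unigene0043726), with a spruce hit, stood at 257 ± 14.2 and 282 ± 0.936 CPM (adjusted p = 0.0567). In the wider list 156 members with a gymnosperm hit had a median of 0.05, with 49 higher and 44 lower, and the other 110 a median of -0.24, with 28 higher and 54 lower. Its most abundant member, RPL31 (Unigene0001442), fell from 836 ± 59.3 to 571 ± 25.1 CPM. The list passed, as lower, without the third August library (adjusted p = 0.0024), without any single September library (0.0304 to 0.0449), with no filter (0.0389), with the stricter filter (0.0406) and with same-hit unigenes summed (0.0395), all at the preset correlation.

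Of 8 tested photosynthesis members, 4 were higher, 2 lower and 2 did not pass (list adjusted p = 0.987). Both that fell are plastid-encoded subunits, psbC (Unigene0045204), from 694 ± 104 to 227 ± 43.4 CPM, and psaA (Unigene0001382), from 36.6 ± 7.90 to 7.34 ± 0.952 CPM. In a list of plastid-encoded transcripts made after the data were seen, 13 of 22 were lower and 3 higher (adjusted p = 0.00067, and 0.253 with an estimated correlation), and 18 of 41 lower and 6 higher with no filter. Mitochondria-encoded transcripts, listed at the same time, moved with them, with 16 of 18 lower and 1 higher, a median log2 fold change of -1.40 and the same adjusted p-values. That 1 higher became 0 without the second August or the second September library and 2 without the third August library or with no filter.

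Antioxidant and defence genes moved both ways. Of 20 antioxidant members 8 were higher and 10 lower (list adjusted p = 0.916), and with no filter 9 of 50 were higher and 19 lower. The abundant catalase CAT2 (Unigene0034227) fell from 3667 ± 209 to 2828 ± 144 CPM while another catalase unigene (CAT7, Unigene0009599) rose from 7.14 ± 0.266 to 80.3 ± 7.04 CPM. Of 42 defence members 13 were higher and 19 lower, or 13 and 20 adjusted over the list alone (list adjusted p = 0.484). The defensin Def2 (Unigene0034129) fell from 504 ± 102 to 220 ± 24.03 CPM. The largest change by rule, Unigene0047620 with a log2 fold change of 4.27, entered that list only through a locus number beginning with PR202. Without such matches, a choice made after seeing the data, 10 members were higher and 18 lower (list adjusted p = 0.255). Of 6 terpene synthases 2 were higher and 3 lower, or 1 lower with same-hit unigenes summed (list adjusted p = 0.916), and the most abundant, a delta-selinene-type synthase (ag5, Unigene0005103), rose from 15.4 ± 4.76 to 35.7 ± 3.42 CPM.

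Of 114 tested pathways of the deposited KEGG annotation, 3 were higher in September and 1 was lower by camera with a preset correlation. Flavonoid biosynthesis had 30 of 52 members higher and 8 lower (adjusted p = 0.0168). All 10 flavonoid list members are among those 52, and of the other 42, 20 were higher and 8 lower. Brassinosteroid biosynthesis had 10 of 14 members higher and 1 lower (0.0185), and linoleic acid metabolism 7 of 11 higher and 1 lower (0.0487). The mRNA surveillance pathway had 60 of 117 members lower and 21 higher (0.0185). With an estimated correlation each had an adjusted p of 0.515, and 8 pathways of 114 had an unadjusted p under 0.05. As examples chosen after their values were seen, a cytochrome P450 of the brassinosteroid pathway (CYP734A1, Unigene0057501), in a family that inactivates brassinosteroids, went from 25.7 to 175 CPM, and the lipoxygenase LOX1.1 (Unigene0068297) from 18.7 to 135 CPM. The nonsense-mediated decay factors UPF1 (Unigene0074608) and UPF2 (Unigene0005245) went from 387 to 231 CPM and from 266 to 158 CPM, and all 4 of these passed the gene test. The linoleic acid call was lost without the first or the third August library (adjusted p = 0.0572 and 0.0594) and with no filter (0.0642). The mRNA surveillance call was lost with gymnosperm best hits only (0.153).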

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

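The tests in this part were chosen only after the results they bear on had been seen.

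The second August library held a set of transcripts that is almost missing elsewhere. In it, 608 unigenes with 30 counts or more had at most 2% of that level in every other library, together 0.911% of its counts, and all fell below the filter for tested genes. Deeper sequencing of that library is argued against by its total count of 13610427, the second lowest of the 6. Among those with a database hit, 0.21% matched a gymnosperm, against 73.3% of all unigenes with as many counts in that library, a value that fits reads from another organism. A difference between kernels of the same month that carried such material and kernels that did not may be biological, and no explanation of that kind was tested.

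Smaller sets, by the same count limits, were found in the first and second August libraries together, with 16 unigenes at 149 to 161 CPM in sum, and in the first September library, with 11 unigenes at 150 CPM in sum. Their best hits differ from those of the 608, where 306 of 466 hits were to Quercus suber and 77 to Carpinus fangiana. All 12 hits of the set of 16 were to Rosaceae genera. The 5 hits of the set in the first September library were to none of these and to no gymnosperm. Unigenes found almost only in all 3 libraries of a month can pass the filter for tested genes. There were 126 in September, with 49 of 88 hits to a gymnosperm and 16 to Quercus suber. August had 45, with 12 of 23 hits to a gymnosperm and 1 to Quercus suber. Whether some of these come from another organism was not tested.

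All 10 tested members of the flavonoid list were higher in September, and with no filter 15 of 25 were higher and 3 lower. Counts moving between list members are argued against by the summed share of the 25 matched unigenes, which rose 7.4-fold. Only 2 tested unigenes outside the list carry a tested member's gene symbol, and they stood at 0 and 1.04 CPM in August, too little to supply the rise. The summed share of the 12 tested unigenes with those symbols rose 8.64-fold, an outcome that these low levels fixed in advance. Copies without the symbol were not covered, and the share of the wider list, which holds further enzymes, rose 1.35-fold. Seed coat left on the September kernels, with its flavonoid and lignin genes, would raise both lists, but with 6 lignin members lower and 9 higher (6 and 5 without the third August library) it cannot be told apart from a rise in the kernel, which expresses lignin genes too. A change with the month of harvest stays open and was not tested apart from these.

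Of 22 plastid-encoded transcripts, 13 were lower in September, psbC among them, and 3 were higher (median log2 fold change -1.66, list adjusted p = 0.00067, and 0.253 with an estimated correlation). The 3 have the symbols rpoB, ycf2 and chlB, stood at 2.24 to 3.45 CPM in September, and have no best hit that names those genes. Other unigenes with the symbols ycf2 (Unigene0000883) and chlB (Unigene0023906) fell, with log2 fold changes of -2.82 and -5.3. A fall of photosynthesis genes as a whole is argued against, since the 27 nuclear members of the wider photosynthesis list had a median of 0.54, with 14 higher and 7 lower. A weaker capture of transcripts without a long poly(A) tail in the September libraries predicts that mitochondria-encoded transcripts fall too, and 16 of 18 were lower and 1 higher, with a median of -1.40 (adjusted p = 0.00067, and 0.253 with an estimated correlation). A lower level of both organelles' transcripts in riper kernels would give the same values, so a biological cause stays open and was not tested.

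With 6 libraries there are 10 splits into 2 groups of 3, too few for a share under 0.05. The months gave 15750 genes, and the highest count of any other split was 0. Every other split mixes the months, so a wide month difference becomes spread within its groups and holds its gene count down. The 0 therefore cannot decide whether the grouping arose by chance. The months were the 1 split of 10 with as many genes. The months gave 6 lists, and the highest other split gave 3, so 1 split of 10 reached 6. The months gave 4 pathways, and 1 other split, the first and the third August library with the third September library against the rest, also gave 4, so 2 splits of 10 reached 4.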

How the results depend on the processing

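The gymnosperm-only fit, the wider lists and the defence list without its PR202 matches were chosen after seeing the data. The 15750 calls stayed within 1.5 times in every run except those given here, and leaving out 1 library gave 15084 to 16143. No gene called in the main test was called in the opposite direction by any alternative that kept unigenes as features. glmTreat against a 2-fold change called 5983 genes, 4233 higher and 1750 lower, because it asks for a larger change. Gymnosperm hits alone gave 9412, 4803 higher and 4609 lower, with 2753 and 1361 at least 2-fold, because fewer genes were tested. On log2(FPKM + 1) the 2-fold counts were 3401 higher and 1921 lower, and with no filter 5135 were at least 2-fold lower; the cause was not tested. Lists passing went from 6 to 0 with an estimated correlation and 15 with fry, which asks another question. Pathways passing went from 4 to 0 with an estimated correlation and 29 with no filter. Without 1 library, 5 to 8 lists and 3 to 5 pathways passed. The lowest correlation within months, 0.98, was 0.95 with log2(CPM + 0.1) and 0.99 with log2(CPM + 10), and the highest between months 0.916 with log2(CPM + 0.1). The fall of L6 (Unigene0000861) reversed to 0.962 when unigenes of its best hit were summed. Of 1744 fold changes of named genes, L6's included, 1697 kept direction and side of the threshold, 38 lost and 8 gained the call. Of 426 list tests 388 did, 16 lost and 22 gained it. Of 756 counts of list members 633 stayed within 1.5 times. Of those that moved, 82 came from settings that change which unigenes a list holds, 20 from leaving out 1 library and 21 from other settings. Deviations from the month means of same-numbered libraries correlated across genes at 0.101, 0.03 and 0.049, and those of differently numbered libraries at -0.091 to 0.051. With 3 libraries per month these weak values cannot decide whether the numbers pair the libraries. With the replicate block 15428 genes, 7 lists (the ribosomal list added) and 4 pathways passed. The self-test, in which far fewer genes changed than were called in the data, recovered 24 of 50 genes changed 1.5-fold and 50 of 50 changed 4-fold. What depth adds to this limit was not measured.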

Other observations

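These observations were chosen after the data were seen. Several abundant transcription factors changed. The dehydration-responsive factor DREB2A (Unigene0012987) fell from 744 ± 35.4 to 128 ± 12.2 CPM (SD, n = 3), its relative DREB2D (Unigene0045275) from 309 ± 56.1 to 39.9 ± 3.49 CPM, and ERF110 (Unigene0008168) from 296 ± 4.42 to 100.86 ± 0.830 CPM. A NAC factor (JA2L, Unigene0050476) fell from 105 ± 14.7 to 11.7 ± 1.33 CPM and the MADS-box gene SOC1 (Unigene0073207) from 70.8 ± 5.19 to 10.5 ± 2.17 CPM. Factors that rose were ASIL2 (Unigene0044311), from 37.1 ± 3.77 to 180 ± 3.85 CPM (log2 fold change 2.28, or 1.12 with the unigenes of its best hit summed), the GRAS factors SCL6 (Unigene0006365), from 33.7 ± 4.82 to 134 ± 17.1 CPM, and NSP1 (Unigene0037664), from 29.7 ± 5.75 to 102 ± 22.4 CPM, and a TCP-family unigene (Unigene0025022), from 1.08 ± 0.0587 to 56.1 ± 11.03 CPM. All passed edgeR's test. By family, 28 of 62 ERF unigenes, the family of the first 3 examples, were lower and 19 higher (median log2 fold change 0.01), 19 of 39 SAP lower and 7 higher (20 and 4 without the third August library), 15 of 27 NAC unigenes were lower and 6 higher, 11 of 22 WRKY lower and 5 higher, 19 of 39 MYB-related lower and 6 higher, and 10 of 17 GRAS higher and 3 lower. None of 26 families passed camera (smallest adjusted p = 0.0907 with a preset and 0.431 with an estimated correlation), where 8 had an unadjusted p under 0.05 with the preset and 1 with the estimated correlation.

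The wider lists added genes that the descriptions had hidden. The cyclin CYCB2-1 (Unigene0001631), which drives cells into mitosis, rose from 1.28 ± 0.402 to 114 ± 12.4 CPM, although the wider cell cycle list had 50 of 131 members higher and 37 lower (adjusted p = 0.456). The PLETHORA-type factor PLT4 (Unigene0009669) rose from 1.58 ± 0.636 to 32.9 ± 8.15 CPM (log2 fold change 4.40, or 1.49 with the unigenes of its best hit summed), and the cell wall invertase CWINV1 (Unigene0008781), which splits sucrose outside the cell, from 1.14 ± 1.20 to 40.8 ± 6.03 CPM (log2 fold change 5.12, or 6.46 without the first August library). The light stress protein ELIP1 (Unigene0008730) had 3887 counts in August and 3 in September, a ratio with a 95% counting interval of 438 to 6211, but the sum of the unigenes with its best hit fell by 3.46 on the log2 scale, against 10.16 for the unigene alone, which fell by 10.90 without the second September library. The abscisic acid receptor PYL8 (Unigene0036951) fell from 14.7 ± 0.670 to 1.83 ± 0.351 CPM, by 3.02 on the log2 scale, against 0.53 for the sum over its best hit (adjusted p = 0.0053). A terpene synthase (ag4, Unigene0071795) fell from 156 ± 41.2 to 15.1 ± 9.89 CPM. In the wider raffinose list 8 of 14 members were higher and 1 lower (adjusted p = 0.0090, and 0.134 with an estimated correlation), with RFS6 (Unigene0071271) rising from 26.3 ± 4.38 to 189 ± 27.5 CPM. The wider storage list had 11 of 15 members higher and 3 lower (adjusted p = 0.0406, and 0.438 with an estimated correlation), while its summed share was 1.02 of its August value. The most abundant member of that list, pine globulin-1 (COS-1, Unigene0000942), rose from 2271 ± 370 to 3255 ± 504 CPM.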
